A study of Mus musculus with 22 samples.

How the data were processed

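RNA from leg muscle and from extraocular muscle (EOM, the muscles that move the eye) of SJL and Balb mice aged 10 and 12 months was measured on 22 Affymetrix arrays. There were 3 arrays for each combination of strain, muscle and age, except the 12-month EOM groups of both strains, which had 2. The deposited values are linear intensities, one per probe set and array, made by the authors with the standard Affymetrix protocol, and the software, background correction and summarization are not stated in the labels. The values show that each array had been scaled to a common target, since the 2%-trimmed mean lay between 1500.8 and 1501.1 on every array. The labels do not say whether replicates were separate animals, so the p-values measure only the spread between samples. The number of arrays limits the precision.

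From the 12488 probe sets, 66 control probe sets were set aside and used only for quality ratios. Of the others, 10833 carried 1 gene symbol, 396 carried several and 1193 carried none. The gene IDs of 10817 of the probe sets with 1 symbol were found in a table of mouse genes for assembly GRCm38.p6, which was used for names only. Values were taken as log2(intensity + 16). The 30% of probe sets with the lowest mean over all arrays were left out, and 8695 were tested. Because the trimmed means already lay within 10% of each other, no further normalization was applied. No probe set tested was named for Dysf or for Myh13, so neither gene is reported.

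A model with a mean for each of the 8 groups was fitted to all 22 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes variances that follow intensity, 14 residual degrees of freedom and 3.63 prior degrees of freedom. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Strain and muscle differences were averaged over both ages with equal weight. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The design was also tried on simulated data with the same groups of arrays. Each value was drawn independently with 1 spread per probe set, so poor arrays and deviations shared by arrays were left out. The shares recovered hold only for that simpler case. With 200 of 8695 probe sets changed, they were counted at log2 changes of 1 and of 2. The share was 41% and 84% for strain in leg and 41% and 80% for strain in EOM. It was 15% and 56% for the difference of the strain effect between muscles, 48% and 87% for EOM against leg in Balb, and 49% and 86% in SJL. It was 16% and 63% for age in SJL leg, 13% and 50% for age in Balb EOM, 7% and 45% for strain in EOM at 12 months, and 3% and 32% for the difference of the age effect between strains in leg.

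Genes were named by a rule fixed before the data were examined, as were the 28 gene lists, the comparisons, their tests and the first set of alternatives. In each strain or muscle comparison the rule took the 10 largest rises and 10 largest falls among the probe sets with 1 symbol and a passing test, using the probe set of a gene with the highest mean. In comparisons between groups it also asked that every array of one group lay above every array of the other within each age. It added up to 4 members of each list with the smallest adjusted p, and Cd55. For the age comparisons and the change of the strain difference with age it took the 5 largest in each direction. Genes chosen after their values were seen are named as such where they appear.

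The lists were tested at the level of 6454 genes with camera, at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. They covered adipocytes, muscle atrophy with stress and metallothioneins, blood, the cell cycle, the circadian clock, complement with its regulators, dysferlin with sarcolemma proteins, endothelium with pericytes, extracellular matrix, EOM-associated genes, fast fibres, fatty acid oxidation, glycogen with glycolysis, and immediate early with heat shock genes. They also covered the interferon response, lymphocytes with NK cells, lysosomes, macrophages with other myeloid cells, melanocytes, MHC with antigen presentation, peripheral nerve myelin, orbital gland with epithelium, oxidative phosphorylation with the TCA cycle, regeneration with immature fibres, retina with lens and cornea, ribosomal proteins, sex-linked genes, and slow fibres.

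Replicate numbers were checked for pairing by correlating the deviations of same-numbered arrays from their group means. At 10 months the correlation between strains was 0.341 to 0.759 over 6 pairs and between muscles 0.293 to 0.69 over 6 pairs. All 4 of the replicate 1 arrays at 10 months had higher 3 prime to 5 prime ratios for Actb than any other array. A deviation shared by these arrays would raise their own correlations and, through the group means, those of replicates 2 and 3. The correlations therefore do not show that the numbers pair the samples, and the labels name no source for a pairing.

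The alternatives fixed with the comparisons were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a 50% filter on dim probe sets, no intensity trend, array quality weights, the replicate number as a block, a fit on only the groups compared, each age alone, each array left out in turn, and for lists all probe sets of a gene. For EOM against leg and the difference between muscles, each block was the leg and EOM array of the same strain, age and replicate number. Leg arrays without such a partner were then left out. Further settings were chosen after the control ratios and values had been seen. These left out the 4 replicate 1 arrays at 10 months, alone or with quantile normalization, fitted those 4 arrays against the rest as a factor, or left out probe sets above 20000 on any array. The results of all 22 arrays are given first, and the counts from the remaining 18 arrays stand beside them.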

Results

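Expression was measured on 22 arrays, with 3 arrays in each of 6 groups and 2 arrays in each of the 12-month EOM groups. The median intensity of an array lay between 423.1 and 650.6, and the ages did not overlap, with 423.1 to 561 on the 12-month arrays and 565.8 to 650.6 on the 10-month arrays. The 4 replicate 1 arrays at 10 months stood apart by Actb, with 3 prime to 5 prime ratios of 5.05 (Balb leg), 9.80 (Balb EOM), 28.7 (SJL leg) and 53.7 (SJL EOM), against 0.847 to 1.93 on the other arrays. By Gapdh they stood apart less, with ratios of 2.17, 18.3, 19.9 and 14.1 in the same order, against 6.71 and 4.66 on the 10-month SJL EOM arrays of replicates 2 and 3 and 0.053 to 1.54 on the rest. The highest intensity on an array was 33366 to 41476 in leg at 12 months and 88609 to 122314 on the 10-month leg arrays of replicates 2 and 3.

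**Figure D1:**
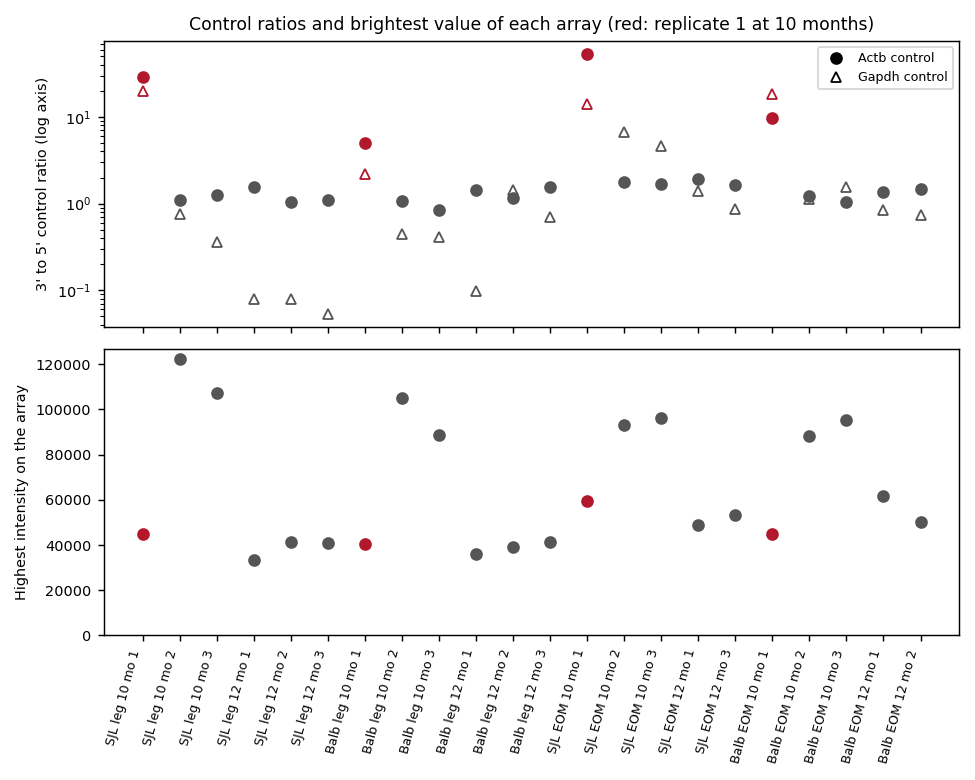
The ratio of 3 prime to 5 prime signal for the Actb and Gapdh controls (upper panel, log axis) and the highest intensity (lower panel) of each of the 22 arrays, with the replicate 1 arrays at 10 months in red. The Actb ratio was 5.05 to 53.7 on the red arrays and 0.847 to 1.93 on the others.

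The comparison of SJL with Balb in leg muscle asks how a strain that carries a dysferlin mutation differs from a strain without it. The effect of the mutation cannot be told apart from that of other differences between the strains. Of 34 macrophage and myeloid genes 6 rose in SJL leg, and the list passed by camera but missed with an estimated correlation (adjusted p = 0.0637). Ctss, a lysosomal protease of antigen-presenting cells, stood at 6235 ± 2270 (SD, n = 6) in SJL and 1530 ± 760 (SD, n = 6) in Balb, a log2 difference of 2.05 (SE 0.35, adjusted p = 0.00248). Actc1, the cardiac actin that skeletal muscle makes while immature, was higher by 1.83 (SE 0.28, adjusted p = 0.00115), and Chrna1, a subunit of the acetylcholine receptor, by 1.75 (SE 0.27, adjusted p = 0.00134). Cd55, an inhibitor of complement, was lower, at 285 ± 73.4 (SD, n = 6) in SJL and 1240 ± 454 (SD, n = 6) in Balb, a log2 difference of -2.02 (SE 0.25, adjusted p = 0.000117). Sspn, a sarcolemma protein of the dystrophin complex, was lower by a log2 difference of -1.79 (SE 0.17, adjusted p = 3.24e-06).

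Of the 34 macrophage and myeloid genes, 0 fell in SJL leg by limma, and 10 rose when adjusted over the list alone. Lyz2 (log2 1.36, SE 0.26), Lgals3 (1.62, SE 0.32) and Mmp12 (2.51, SE 0.57) were among the 6. The list's median log2 difference was 0.61 and its adjusted p by camera was 1.27e-15. The 19 MHC and antigen presentation genes had a median of 0.56 (adjusted p = 2.17e-07), with an adjusted p = 0.0859 with an estimated correlation. Of these, Ctss, which is also in the macrophage list, rose over all probe sets, and 2 rose when adjusted over the list alone. H2-Ea, a class II gene outside the rule for named genes in leg and chosen after its values were seen, was lower (log2 -2.78, SE 0.41, adjusted p = 0.000908). H2-K1, an MHC gene also chosen after its values were seen, was higher in SJL leg at 1 probe set (log2 2.02, adjusted p = 6.56e-07 by limma). Averaged over leg and EOM its other probe sets had 0.279 and 0.322, beside 2.192 for this one. Of 35 regeneration and immature fibre genes, 5 rose and 6 rose when adjusted over the list alone, with a median of 0.06 (adjusted p = 0.02), and an adjusted p = 0.29 with an estimated correlation. The 21 interferon genes had a median of 0.37 (adjusted p = 0.00681), with an adjusted p = 0.29 with an estimated correlation, and 1 gene rose when adjusted over the list alone. None of these passed over all probe sets by limma, with 6 at an unadjusted p under 0.05.

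Other lists gave no call in leg by camera on all 22 arrays. Without the replicate 1 arrays at 10 months, 6 of them passed by camera (adjusted p = 0.00745 to 0.035), higher in SJL for atrophy with stress, complement, extracellular matrix and lysosomes, and lower for fatty acid oxidation and for immediate early with heat shock genes. None of the 6 passed with an estimated correlation. Among 13 atrophy, stress and metallothionein genes, 3 rose and 1 fell, including Odc1 (1.42, SE 0.20) and Ddit4 (-1.05, SE 0.22), and 5 rose and 2 fell when adjusted over the list alone. The largest strain differences of any gene named in leg were in Phkg1, a subunit of the kinase that activates glycogen breakdown (5.84, SE 0.26), and 1 probe set of Pdxdc1 (-5.27, SE 0.32). The other Pdxdc1 probe sets that passed were higher in SJL leg, by 2.70 (adjusted p = 6.17e-05) and 2.47 (adjusted p = 2.49e-05). Kcnab1, a potassium channel subunit, was higher by 3.83 (SE 0.36). In all, 64 probe sets were higher and 59 lower of 8695 tested. The 18 arrays left without the replicate 1 arrays at 10 months gave 354 and 357, and all 123 calls were kept.

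The comparison of the strains in EOM asks the same question in eye muscle. Of 14 slow-fibre genes 3 rose in SJL EOM, and the list passed by camera but missed with an estimated correlation (adjusted p = 0.418). Myh7, the slow myosin heavy chain, stood at 39460 ± 7790 (SD, n = 5) in SJL and 8883 ± 2820 (SD, n = 5) in Balb, a log2 difference of 2.12 (SE 0.35, adjusted p = 0.00264), and the other Myh7 probe set had 0.85. Myl2 was higher by 2.10 (SE 0.31, adjusted p = 0.000929) and Tnnc1, the slow troponin C, by 2.67 (SE 0.45, adjusted p = 0.00323). Muc1, a mucin (-1.87, SE 0.38, adjusted p = 0.0175), and Elf3, an epithelial transcription factor (-1.93, SE 0.36, adjusted p = 0.00848), were lower in SJL EOM.

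Of the 14 slow-fibre genes, 0 fell in SJL EOM by limma, and 6 rose and 1 fell when adjusted over the list alone. Their median was 0.46 (adjusted p = 3.35e-05 by camera and 0.132 by fry). Of 12 orbital gland and epithelium genes, 2 fell, and 4 fell when adjusted over the list alone. Their median was -0.54 (adjusted p = 1.33e-05), with an adjusted p = 0.0183 with an estimated correlation. Without the 4 replicate 1 arrays at 10 months this estimated-correlation value was 0.374. The 34 macrophage and myeloid genes had a median of -0.09 (adjusted p = 0.945), and 0 passed in either direction by limma, with 1 at an unadjusted p under 0.05. Sspn (-1.90, SE 0.19) and Rgs5, a pericyte marker (-1.90, SE 0.27), were lower, though the other Rgs5 probe set had -0.05. H2-Ea (-4.03, SE 0.46), Krt6a, an epithelial keratin (-2.48, SE 0.25), and Pglyrp1, a bactericidal protein (-2.98, SE 0.41), were lower too. Cd55 had a log2 difference of -1.18 (SE 0.28, adjusted p = 0.0557), which did not pass.

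In EOM 32 probe sets were higher and 49 lower, a balance that median centring turned to 40 and 36. The 18 arrays gave 326 and 392, and all 81 calls were kept. Without Balb EOM 12-month replicate 2 the total was 47, and a fit on only the groups compared gave 35. Phkg1 (5.03, SE 0.29) and the same Pdxdc1 probe set (-4.57, SE 0.36) had large differences in EOM as in leg, and the other Pdxdc1 probe sets were again higher in SJL, by 2.29 (adjusted p = 0.00167) and 2.36 (adjusted p = 0.000215). Across both muscles 18 probe sets were higher in each, against 0.236 expected by chance (Fisher's exact test, one-sided, p = 1.28e-31), and 23 were lower in each, against 0.332 (p = 5.03e-39). Expected counts here and below, and these p-values, take probe sets and comparisons as independent. Some probe sets shared a gene and the comparisons came from one fit, so they are only a rough guide.

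**Figure D2:**
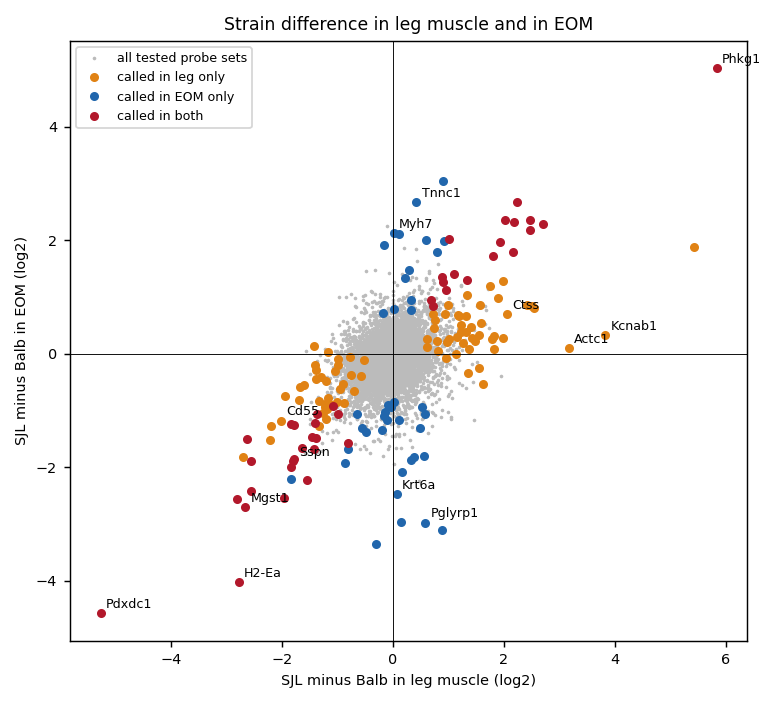
The SJL minus Balb log2 difference of each of 8695 probe sets in leg muscle (horizontal axis) and EOM (vertical axis), with colours for those that passed in leg, in EOM or in both. The 41 probe sets that passed in both muscles in the same direction, Phkg1 and Pdxdc1 among them, lie along the diagonal.

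The test of the difference between muscles asks whether strain effects in leg and EOM were unequal. Kcnab1, higher in SJL leg, had a larger strain difference in leg than in EOM (difference of log2 differences 3.50, SE 0.54, adjusted p = 0.0125). Pglyrp1 (3.56, SE 0.55, adjusted p = 0.0125), Krt6a (2.55, SE 0.33, adjusted p = 0.00392), Krt4 (1.46, SE 0.24, adjusted p = 0.0154) and Asprv1, a protease of skin epithelium (1.79, SE 0.30, adjusted p = 0.0154), also differed, and each was lower in SJL EOM than in Balb EOM. None of these passed for strain in leg (adjusted p = 0.172 to 0.979 by limma). A second Actc1 probe set, chosen after its values were seen, differed by 3.08 (SE 0.52, adjusted p = 0.0154), being 3.17 higher in leg and 0.10 higher in EOM. On 10-month replicates 2 and 3 it already read 52683 and 51669 in Balb EOM, beside 1878 and 1752 in Balb leg. A rise of 3.17 from there would pass 122314, the highest intensity on any array, so EOM could not have shown it. Cd55 did not pass (-0.84, SE 0.38, adjusted p = 1).

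Lists differed between muscles by camera. The macrophage list had a median of 0.72 more in leg (adjusted p = 3.22e-12), with an adjusted p = 0.0755 with an estimated correlation, and the slow-fibre list -0.56 (adjusted p = 6.55e-05), with an adjusted p = 0.208 with an estimated correlation. The orbital gland and epithelium list had 0.70 (adjusted p = 6.34e-05), with an adjusted p = 0.039 with an estimated correlation, or 0.153 without the 4 replicate 1 arrays at 10 months. Of 34 macrophage genes 0 passed over all probe sets by limma, with 9 at an unadjusted p under 0.05, and 2 rose when adjusted over the list alone. Of the slow-fibre genes 4 fell and of the gland genes 3 rose when adjusted over the list alone, and 0 of either list passed over all probe sets by limma, with 4 of each at an unadjusted p under 0.05. In all, 8 probe sets were higher and 0 lower by limma, with 404 at an unadjusted p under 0.05. Quantile normalization gave 9 and 2, so the share that was higher was 100% as deposited and 81.8% under it. The 18 arrays gave 90 and 66. The total was 1 without Balb EOM 12-month replicate 2 or SJL EOM 12-month replicate 1, 14 without SJL leg 10-month replicate 1, and 21 with the replicate block. Only the 10-month arrays gave 0 by limma, with 147 at an unadjusted p under 0.05, and only the 12-month arrays gave 56.

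**Figure D3:**
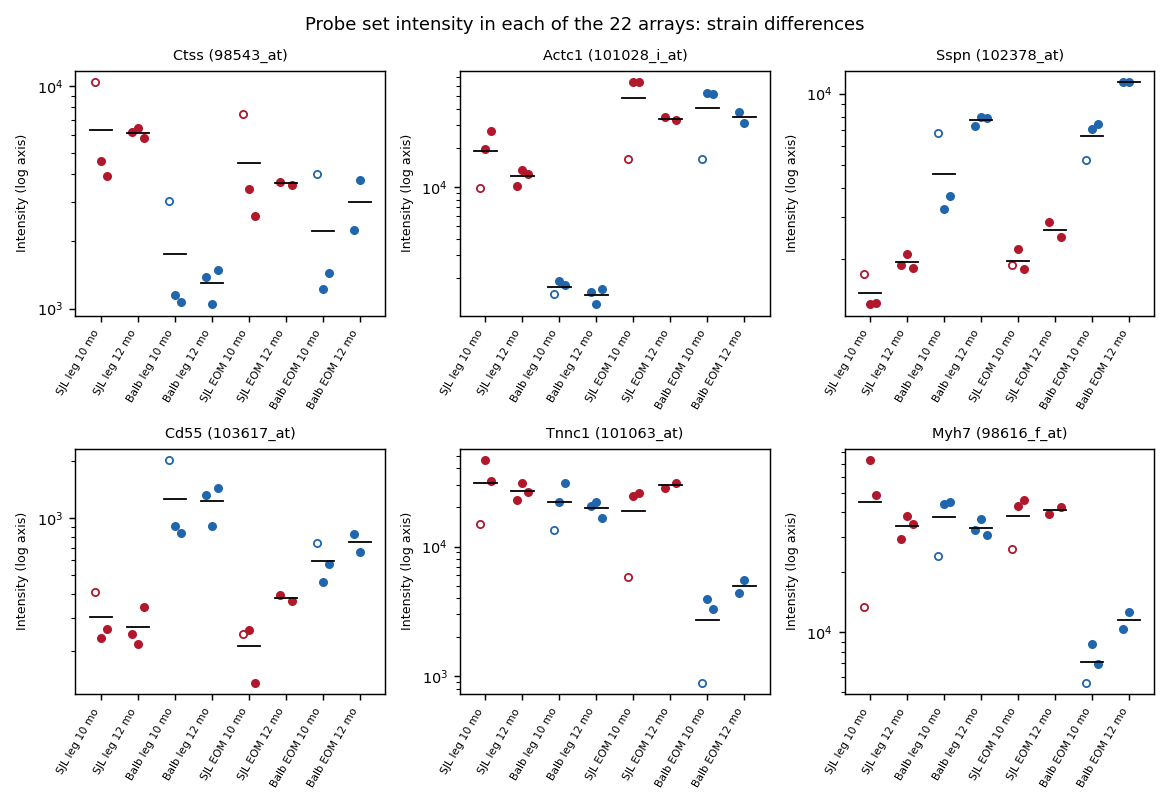
Intensity on a log axis of 6 probe sets in each of the 22 arrays, with SJL in red, Balb in blue, open points for the replicate 1 arrays at 10 months and bars for group means. Ctss and the second Actc1 probe set were higher in SJL leg, Sspn and Cd55 lower in SJL leg, and Tnnc1 and Myh7 higher in SJL EOM.

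The comparison of EOM with leg asks how the muscles differ within each strain. Myh3, the embryonic myosin heavy chain, stood at 13870 ± 2390 (SD, n = 5) in Balb EOM and 337.7 ± 105 (SD, n = 6) in Balb leg, a log2 difference of 5.37 (SE 0.27, adjusted p = 1.09e-09), and of 4.59 (SE 0.27, adjusted p = 7.79e-09) in SJL. Myom2, an M-band protein of fast fibres, was lower in EOM, with log2 differences of -5.10 (SE 0.30) in Balb and -5.03 (SE 0.30) in SJL. Bpifa2 (5.87, SE 0.36, in Balb and 3.66, SE 0.36, in SJL) and Obp1a (6.29, SE 0.76, and 5.47, SE 0.76), which glands secrete, were higher in EOM. Hoxc9, a gene of trunk and limb position, was lower in EOM, with log2 differences of -3.15 (SE 0.40) in Balb and -3.34 (SE 0.40) in SJL.

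Of 10 peripheral nerve myelin genes, 7 rose in EOM in Balb and 7 in SJL, and the same numbers when adjusted over the list alone. The medians were 1.09 (adjusted p = 4.02e-06) and 1.29 (adjusted p = 2.66e-07), and both calls held with an estimated correlation (adjusted p = 0.0111 and 0.0034). Erbb3 (2.08, SE 0.19, and 2.28, SE 0.19) and Pmp22 (1.89, SE 0.23, and 2.25, SE 0.23), which Schwann cells make, were among them. Of 17 adipocyte genes, 10 rose in Balb and 7 in SJL, 11 and 8 when adjusted over the list alone (adjusted p = 4.02e-06 and 0.000347), such as Scd2 (2.02, SE 0.19, and 1.98, SE 0.19). Both calls held with an estimated correlation (adjusted p = 0.0111 and 0.0486), but neither did without the replicate 1 arrays at 10 months (adjusted p = 0.211 and 0.45). Of 48 extracellular matrix genes, 18 rose in Balb and 7 in SJL, 23 and 14 when adjusted over the list alone (adjusted p = 2.5e-05 and 0.00679), with an adjusted p = 0.0111 and 0.0588 with an estimated correlation. Of 20 endothelium and pericyte genes, 7 and 9 rose, 9 and 13 when adjusted over the list alone (adjusted p = 0.00509 and 3.74e-06), with an adjusted p = 0.0506 and 0.0034 with an estimated correlation. Of 14 circadian genes, 4 and 2 fell, the same numbers when adjusted over the list alone (adjusted p = 0.00442 and 0.0165). Both calls held with an estimated correlation (adjusted p = 0.024 and 0.0486), but neither did without the replicate 1 arrays at 10 months (adjusted p = 0.0506 and 0.129).

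Of 14 slow-fibre genes, 6 fell and 0 rose in Balb EOM against leg by limma, 7 fell and 1 rose when adjusted over the list alone, with a median of -1.06 (adjusted p = 0.000519) and an adjusted p = 0.216 with an estimated correlation. The mean turned from -1.06 to 0.83 (adjusted p = 0.271) when probe sets above 20000 were left out, a setting chosen after the data were seen that kept 3 of the genes. Myl3 had a log2 difference of -5.16 (SE 0.55) and Tnnc1 of -2.59 (SE 0.43). In SJL the list had a median of 0.02, a mean of -0.32 and a downward test that did not pass (adjusted p = 0.28), with 3 falls and 1 rise. Of 12 orbital gland and epithelium genes, 4 rose in Balb, also when adjusted over the list alone (median 0.64, adjusted p = 0.00509), with an adjusted p = 0.0722 with an estimated correlation, and 0 in SJL by limma, with 1 at an unadjusted p under 0.05 (median 0.22, adjusted p = 0.736). Of 34 macrophage and myeloid genes, 6 rose in Balb, also when adjusted over the list alone (adjusted p = 0.00308), with an adjusted p = 0.321 with an estimated correlation. In SJL 0 of them rose by limma and 1 fell, with 2 at an unadjusted p under 0.05, and their median was -0.15 with a downward test that did not pass (adjusted p = 0.141).

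Further lists passed in Balb, and whether Balb and SJL differ in them is given by the test of the difference between muscles. MHC and antigen presentation had 3 of 19 genes higher, 6 when adjusted over the list alone (adjusted p = 0.00568), with an adjusted p = 0.274 with an estimated correlation. The interferon response had 3 of 21, 4 when adjusted over the list alone (adjusted p = 0.0368), with an adjusted p = 0.363 with an estimated correlation. Regeneration and immature fibres had 12 of 35 higher and 4 lower, 16 and 5 when adjusted over the list alone (adjusted p = 0.0368), with an adjusted p = 0.289 with an estimated correlation. Without the replicate 1 arrays at 10 months the regeneration list missed by camera (adjusted p = 0.0639), and complement (0.0316) and lysosomes (0.0223) passed, neither of them with an estimated correlation. Kcnab1, by contrast, was lower in SJL EOM than in SJL leg (-4.65, SE 0.38).

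In Balb 758 probe sets were higher and 423 lower in EOM, and in SJL 534 and 297. The excess of higher calls was not firm, since median centring gave 428 higher and 691 lower in Balb and 406 and 376 in SJL. The calls shared by the strains were 354 higher, against 46.6 expected, and 213 lower, against 14.4. Quantile normalization moved the median log2 difference of all probe sets in Balb from 0.11 to -0.01. The 18 arrays gave 1601 and 1300 in Balb and 1487 and 1193 in SJL, or 1409 and 1473 and 1382 and 1335 with quantile normalization as well, and the replicate block gave totals of 1772 and 1375. The 10-month arrays alone gave 81 and 64, and the 12-month arrays alone 2433 and 1949. In Balb the total was 679 without EOM 12-month replicate 1 and 700 without replicate 2. In SJL it was 483 without EOM 12-month replicate 1, 535 without EOM 12-month replicate 3, 1270 without leg 10-month replicate 1, and 487 in a fit on only the groups compared.

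**Figure D4:**
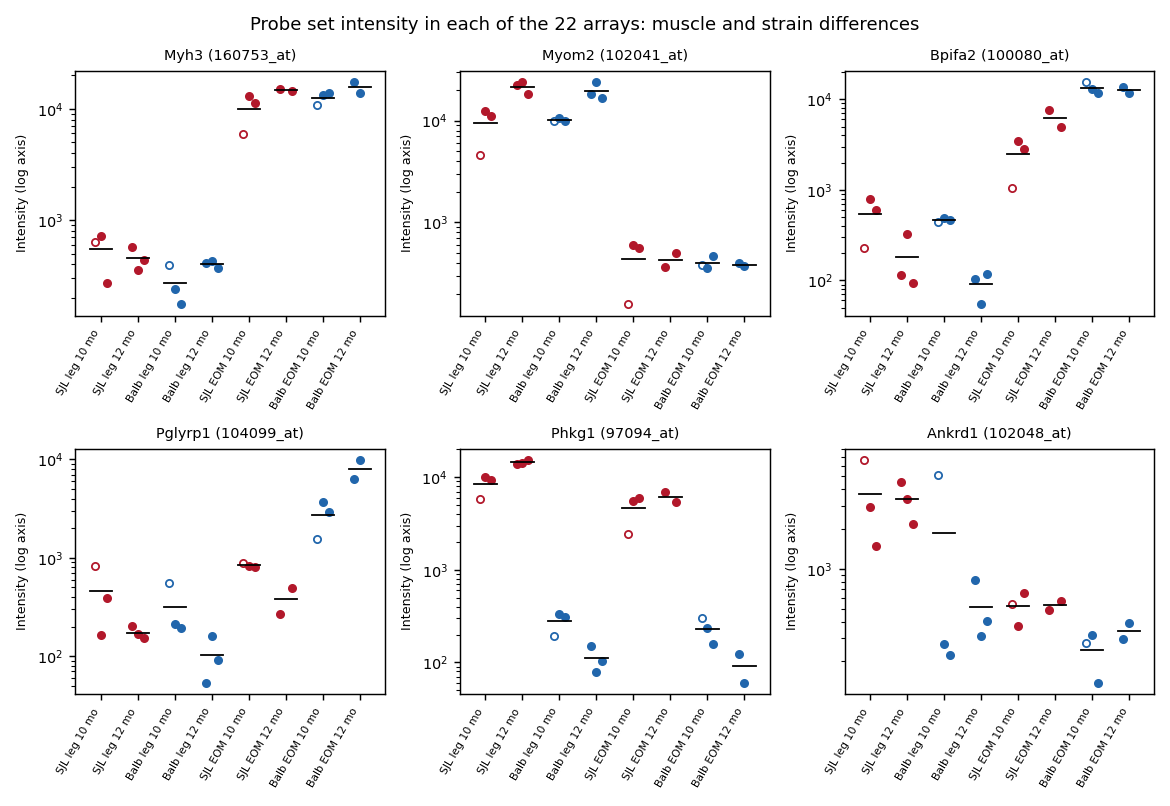
Intensity on a log axis of 6 probe sets in each of the 22 arrays, with SJL in red, Balb in blue, open points for the replicate 1 arrays at 10 months and bars for group means. Myh3 and Bpifa2 were higher in EOM, Myom2 lower in EOM, Pglyrp1 lower in SJL EOM than in Balb EOM, Phkg1 higher in SJL in both muscles, and Ankrd1 lower in SJL EOM than in SJL leg.

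The comparison of 12 with 10 months asks what differed between the ages in each strain and muscle. The arrays of the 2 ages stood apart in median intensity, so a difference between the sets of arrays cannot be told apart from age in the values that follow. Of 14 fast-fibre genes 6 fell at 12 months in SJL leg and 6 in Balb leg, and the list did not pass by camera (adjusted p = 0.11 and 0.0551). Atp2a1, the calcium pump of fast fibres, fell by 4.36 on the log2 scale (SE 0.91, adjusted p = 0.00197) in SJL and by 4.29 (SE 0.91, adjusted p = 0.00332) in Balb. Actn3, the fast-fibre actinin, fell by 4.17 (SE 0.71, adjusted p = 0.000394) and by 3.66 (SE 0.71, adjusted p = 0.00172), with 3 arrays in each group. A second Actn3 probe set, chosen after its values were seen, fell by 0.75 (SE 0.23, adjusted p = 0.0245) in SJL, and its log2 difference in Balb was -0.49 (SE 0.23, adjusted p = 0.163). The heat shock gene Hspa1b rose in SJL leg by 3.21 (SE 0.65, adjusted p = 0.00158).

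Further genes were chosen after their values were seen. The brighter Aldoa probe set fell by 3.31 (SE 0.95, adjusted p = 0.0152) in SJL leg and by 3.38 (SE 0.95, adjusted p = 0.0177) in Balb leg. The dimmer Aldoa probe set had log2 differences of -0.48 (SE 0.49, adjusted p = 0.503) and -0.27 (SE 0.49, adjusted p = 0.764), whose sign was positive under quantile normalization in both strains. Without the replicate 1 arrays at 10 months its values were -1.17 (adjusted p = 0.00377) and -0.74 (adjusted p = 0.0508). Myh4, the fastest myosin heavy chain, had -0.11 (SE 2.31, adjusted p = 0.975) in SJL and -2.91 (SE 2.31, adjusted p = 0.434) in Balb. The SJL value was 0.42 under quantile normalization and 0.35 with median centring. Without the replicate 1 arrays at 10 months Myh4 fell by 4.26 (adjusted p = 0.00116) in SJL and fell by 4.70 (adjusted p = 0.000735) in Balb.

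In EOM, Fgfr3, a fibroblast growth factor receptor, fell by 4.25 (SE 0.67, adjusted p = 0.000644) in SJL EOM, and Otog fell by 3.42 (SE 0.60, adjusted p = 0.00323) in Balb EOM. Brd2, a chromatin reader, rose in both, by 2.79 (SE 0.59, adjusted p = 0.00455) in SJL and 2.39 (SE 0.59, adjusted p = 0.0203) in Balb. Zbtb17, a transcription factor, rose in SJL leg (2.76, SE 0.58), Balb leg (2.44, SE 0.58) and SJL EOM (2.70, SE 0.65).

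The 14 fast-fibre genes had medians of -0.72 in SJL leg and -1.50 in Balb leg, and the same 6 and 6 falls when adjusted over the list alone. Without the replicate 1 arrays at 10 months, 13 fell in SJL leg and 10 in Balb leg, also when adjusted over the list alone, with medians of -1.84 and -2.16, and the list passed by camera (adjusted p = 5.27e-05 and 6.14e-05) and missed with an estimated correlation (adjusted p = 0.383 and 0.36). The highest intensity on any array in leg at 12 months was 41476, beside 122314 at 10 months, and the Gapdh 3 prime control read 814.6 to 2756 on the 12-month leg arrays. On the 10-month leg arrays of replicates 2 and 3 it read 20266 to 56518. The Gapdh 5 prime control read 49231.7 to 74266.5 on those 10-month arrays and 17592.6 to 34936.4 on the 12-month SJL leg arrays, a smaller drop in proportion. On the 12-month Balb leg arrays it read 9514 for replicate 1 and 1219.7 and 1154.4 for replicates 2 and 3. Of 12 orbital gland and epithelium genes, 5 fell at 12 months in SJL leg and 4 in Balb leg, and 8 and 5 when adjusted over the list alone. Their medians were -1.40 (adjusted p = 0.0205) and -1.17 (adjusted p = 0.012), with an adjusted p = 0.311 and 0.243 with an estimated correlation. Lists of other tissues were low beside it and did not pass by camera. Retina with lens and cornea had medians of -0.92 in SJL leg (4 of 15 fell, adjusted p = 0.107) and -0.80 in Balb leg (3 fell, adjusted p = 0.0551), and lymphocytes with NK cells -0.94 (5 of 13 fell, adjusted p = 0.162) and -0.70 (4 fell, adjusted p = 0.141). Melanocytes had -1.08 in SJL leg (2 of 5 fell, adjusted p = 0.181) and -0.74 in Balb leg (0 fell by limma, with 1 at an unadjusted p under 0.05, adjusted p = 0.66). The dimmest class of probe sets by mean on the 10-month leg arrays (3467 probe sets) had medians of -0.263 in SJL leg and -0.197 in Balb leg. The 237 with means from 10000 to 20000 had 0.236 and 0.193, and the 181 over 20000 had -0.198 and -0.309. Whether the gland list fell beyond probe sets of its own brightness was not tested. Its fall alone therefore does not show a loss of gland transcripts with age. In Balb EOM the 19 MHC and antigen presentation genes had a median of 0.90 (adjusted p = 0.0224), with an adjusted p = 0.646 with an estimated correlation, 1 rise and 1 fall, and 6 rises and 1 fall when adjusted over the list alone. Without the replicate 1 arrays at 10 months it missed by camera (adjusted p = 0.165).

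The counts of probe sets higher and lower at 12 months were 518 and 1680 in SJL leg, 279 and 1379 in Balb leg, 230 and 1067 in SJL EOM, and 107 and 571 in Balb EOM. Quantile normalization moved the median log2 difference of all probe sets from -0.10 to 0.10 in SJL leg, from -0.08 to 0.09 in Balb leg, from -0.13 to 0.03 in SJL EOM and from -0.06 to 0.05 in Balb EOM. The share that was higher moved from 23.6% to 35.6%, from 16.8% to 28.2%, from 17.7% to 28.7% and from 15.8% to 26.2%. Median centring turned the balance to 1731 higher and 1044 lower in SJL leg, 989 and 745 in Balb leg and 764 and 601 in SJL EOM, and gave 186 and 286 in Balb EOM, so the excess of lower calls was not firm. In the same order, the 18 arrays gave 1918 and 2332, 1619 and 2056, 1049 and 1477, and 914 and 986, and with quantile normalization as well 2294 and 1658, 1935 and 1441, 1215 and 1046, and 1105 and 887. In SJL EOM the total was 406 without the 12-month replicate 1 and 702 without the 12-month replicate 3. In Balb EOM it was 366 without the 12-month replicate 1, 74 without the 12-month replicate 2, 335 without the 10-month replicate 1 and 438 without the 10-month replicate 2. Fitted on only the groups compared, limma gave 0 in SJL EOM, with 1948 at an unadjusted p under 0.05, and 0 in Balb EOM, with 1466.

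The strains were also compared at each age. In leg, 18 probe sets were higher and 18 lower in SJL at 10 months, and 37 higher and 38 lower at 12 months. Of these, 14 were higher at both ages, against 0.0766 expected, and 13 were lower at both, against 0.0787. In EOM the counts were 13 and 12 at 10 months, and 14 and 30 at 12 months, with 8 higher at both ages, against 0.0209 expected, and 8 lower at both, against 0.0414. Sspn, for example, had log2 differences of -1.59 at 10 months and -1.99 at 12 months in leg, and of -1.73 and -2.07 in EOM. The test of whether the strain difference changed with age called 0 probe sets in leg and 0 in EOM by limma, with 264 and 257 at an unadjusted p under 0.05. With the 18 arrays it called 15 and 8, and in EOM it called 1 without Balb 12-month replicate 1, SJL 12-month replicate 1 or SJL 10-month replicate 1.

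The counts at each age moved with single arrays. In leg at 10 months the total was 55 without Balb replicate 1, 23 without Balb replicate 2, 21 without Balb replicate 3 and 20 without SJL replicate 3. In leg at 12 months it was 41, 32 and 35 without Balb replicates 1, 2 and 3, and 37, 39 and 35 without SJL replicates 1, 2 and 3. In EOM it was 16 at 10 months without Balb replicate 3, and 26 and 25 at 12 months without Balb replicates 1 and 2. The 18 arrays gave totals of 296 and 478 in leg and 405 and 264 in EOM. At 10 months in EOM the Gapdh ratios on those arrays still differed by strain. They were 6.71 and 4.66 in SJL and 1.14 and 1.54 in Balb, so RNA quality cannot be told apart from strain there. A fit on only the groups compared, given with the processing below, ended nearly all calls at 10 months in both muscles. It raised the counts at 12 months.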

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

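The tests of other explanations here, and the settings without the 4 replicate 1 arrays at 10 months, were chosen after the results were seen; the counts over other splits of the arrays were planned. The strain difference was unequal in leg and EOM, by the test of the difference, for 8 probe sets. Leg minus EOM was 4 and 3.56 for the Pglyrp1 probe sets, 3.5 for Kcnab1, 3.11 and 2.55 for the Krt6a probe sets, 3.08 for Actc1, 1.79 for Asprv1 and 1.46 for Krt4. By camera it was also unequal for 10 lists, with medians of 0.38 for adipocytes, 0.32 for atrophy with stress and metallothioneins, -0.23 for endothelium with pericytes, 0.27 for extracellular matrix, 0.43 for the interferon response, 0.24 for lysosomes, 0.72 for macrophages, 0.27 for MHC with antigen presentation, 0.7 for orbital gland with epithelium and -0.56 for slow fibres. With an estimated correlation the orbital gland list alone kept its call, with an adjusted p = 0.039, or 0.153 without the 4 arrays. Without them the endothelium list missed by camera (adjusted p = 0.091). The Pglyrp1, Krt6a, Asprv1 and Krt4 probe sets did not pass for strain in leg (adjusted p = 0.172 to 0.979 by limma). The Pglyrp1 probe set with 3.56 was dim in leg, at 53.7 to 550.3 in Balb leg and 1551.5 to 9868 in Balb EOM. Whether the amount of gland or epithelium in the EOM samples lay behind these calls was not tested. The Actc1 probe set was too bright in EOM to show the difference seen in leg.

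Of 100 splits of the arrays, 1 (the real one) called 123 probe sets for strain in leg, and the highest other called 86 with both replicate 1 arrays at 10 months on one side. Of 60 splits for strain in EOM, 1 called 81 and the highest other 28. Of 100 splits each, 1 called 1181 for EOM against leg in Balb (highest other 232) and 1 called 831 in SJL (highest other 239). For the difference between muscles 3 of 100 splits called as many as the real 8, and the highest other called 72, several times the real count, which points to a structure of the samples. That split put the replicate 1 arrays at 10 months together, and with them apart the highest other was 3. Without those arrays the real split called 156. For strain in leg, strain in EOM and EOM against leg in each strain, chance can be excluded over all splits drawn, at a share under 0.05. For the difference between muscles it cannot. Its splits exchange the strains within each muscle and age, so they also remove the strain effect that the muscles share. Among splits that part as many same-numbered pairs it cannot, since in the order given only 12, 15, 16, 11 and 4 others were drawn, calling at most 2, 8, 60, 0 and 0 by limma. For strain at 10 months, the 3 other splits that also part all 3 same-numbered pairs called at most 1 in leg and 0 in EOM by limma. With 10 splits a share under 0.05 cannot be reached for age in SJL leg (2198, highest other 0 by limma), age in Balb leg (1658, highest other 0), strain in leg at 10 months (36, highest other 14) and 12 months (75, highest other 1) and strain in EOM at 10 months (25, highest other 2). For the change of the strain difference with age in leg, the real count was 0 by limma, so 100 of 100 splits reach it and the comparison says nothing on chance. The highest other called 86, which also points to a structure of the samples.

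Of 14 slow-fibre genes 3 were higher in SJL EOM than in Balb EOM, and the list's call was lost with an estimated correlation (adjusted p = 0.418). Leg muscle or leg RNA in the SJL samples would raise other leg-enriched transcripts alike. The slow-fibre genes implied a leg share of 96.3% (6 genes, quartiles 41.2 and 104.5), and 18 other leg-enriched genes a median of 0.2% (quartiles -3 and 1.9). This cannot decide the question, because the 6 were picked for a rise in SJL EOM. The 18 had to pass as lower in EOM than in leg in SJL as well as in Balb, which favours a small share. Less gland and epithelium would raise fast-fibre genes too, and their median change was 0.00 (14 genes, quartiles -0.13 and 0.17), below the smallest called slow-fibre rise of 2.10. That value cannot decide it, because fast-fibre genes such as Atp2a1 and Myh4 already had means above 40000 on 10-month EOM arrays. The highest intensity on a 12-month EOM array was 61883, so such genes had little room to rise. Leg muscle or leg RNA in the SJL samples stays open, and so does less gland and epithelium in them. A different fibre composition in SJL EOM, or a different mix of the eye muscles taken, may remain too and was not tested.

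The strain differences shared by both muscles covered 41 probe sets. The replicate 1 arrays at 10 months are not their source, since all 41 kept their call without those arrays. Over 21 pairs of probe sets of 13 genes, the median ratio of the other probe set's difference to the called one was 0.13 (quartiles -0.09 and 0.36), which is consistent with a sequence or transcript difference between the strains at one probe set for many of them. The Pdxdc1 probe sets oppose each other and make up 6 of the 21 pairs. A difference in expression stays open for the genes with 1 probe set and for those whose other probe set followed, such as Rhou (-1.55 beside the called -1.22) and 1 of the 2 others of Vcp (-1.87 beside -1.55).

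Bright probe sets in leg were compared between ages as 2 sets, and the first, 294 above 20000 on any 10-month leg array, had a median change of -0.07 (quartiles -0.43 and 0.2), so it held no clear fall, and its -0.19 without the replicate 1 arrays at 10 months and the -0.18 of its dim probe sets (quartiles -0.92 and 0.42) leave every cause open. Over 54 of its genes bright minus dim probe sets gave -0.06 (quartiles -0.43 and 0.78), which decides nothing on compression, because a count made after that value was seen found just 10 bright ones with a mean above 33366, the lowest of the highest intensities on the 12-month leg arrays, and over these it was 0.16 (quartiles -0.37 and 0.44). A second set, 60 probe sets with a mean above 40000 on the 10-month EOM arrays, was chosen after the first result, because the highest intensity on a 12-month leg array was 41476; its median was -0.61 (quartiles -1.1 and -0.38) with all arrays and -1.08 (quartiles -1.75 and -0.66) without the replicate 1 arrays, so they are not its source. Its 39 members outside the muscle lists had a median of -0.55 (quartiles -0.94 and -0.28), beside -0.9 for the 21 in those lists (quartiles -1.61 and -0.5). This does not decide whether a loss of fibre and glycolytic transcripts was the whole cause. The 39 hold other muscle transcripts, such as Acta1 (-2.47 in SJL leg and -2.63 in Balb leg) and Ryr1 (-1.07 and -0.99), which such a loss could lower too. A cap on bright signals there cannot be told apart from lower expression, because bright minus dim probe sets, a test made a condition only after the -0.55 was seen, gave -0.34 (quartiles -0.48 and 0.52) over just 7 genes, and 6 fast-fibre probe sets too dim for a cap had a median of -0.8 with quartiles of -1.09 and 0.06.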

How the results depend on the processing

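The settings that treat the 4 replicate 1 arrays at 10 months or bright probe sets apart were chosen after the data were seen; the others were planned. Of 348 alternative counts 237 stayed within 1.5 times the value reported. Of 7358 values for called genes 619 kept their direction and missed the threshold and 0 turned; of 1128 list values 127 did so and 1 turned. Estimated correlation ended 25 of 35 list calls, fry 13 and all probe sets of a gene 7. Except where stated, the cause was not tested. Signal over background limits what can be seen for the dimmest 30% of probe sets.

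With quantile normalization the total was 1040 for age in Balb leg and 40 for strain in leg at 12 months. With array quality weights the totals were 457 for strain in leg, 551 in EOM, 114 for their difference, 2911 for EOM against leg in Balb and 2426 in SJL. For age they were 3612 in SJL leg, 2476 in SJL EOM, 3626 in Balb leg and 1949 in Balb EOM. For strain at each age they were 105 and 610 in leg, 356 and 228 in EOM, and 9 for strain by age in EOM. Strain by age in EOM called 2 without a filter and 1 with the 50% filter.

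The fit on only the groups compared has fewer arrays. It gave 35 for strain in EOM, 487 for EOM against leg in SJL, 1 and 629 for strain in leg at 10 and 12 months, 116 in EOM at 12 months and 1 for strain by age in leg. By limma it gave 0 for age in SJL EOM (1948 at an unadjusted p under 0.05), 0 for age in Balb EOM (1466) and 0 for strain in EOM at 10 months (225). The 10-month arrays alone gave 81 for EOM against leg in Balb, 64 in SJL and 0 for the difference of the strain effect by limma (147 at an unadjusted p under 0.05). The 12-month arrays alone gave 2433, 1949 and 56.

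Same-numbered arrays at 12 months correlated by -0.081 to -0.009 between strains (4 pairs) and -0.015 to 0.014 between muscles (4 pairs), and by -0.011 to 0.16 between ages (10 pairs). They showed no clear shared deviation there, which cannot decide whether the samples were paired. The replicate block gave 1772 for EOM against leg in Balb, 1375 in SJL and 21 for the difference of the strain effect. In those comparisons it paired leg and EOM arrays of the same strain, age and replicate number. Leg arrays without such a partner were left out. The block on replicate number alone moved no other count over 1.5 times, with 48 in leg and 37 in EOM for strain at 10 months.

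Without the 4 arrays the totals were 711, 718 and 156 for strain in leg, in EOM and their difference, 2901 and 2680 for EOM against leg in Balb and SJL, 4250, 2526, 3675 and 1900 for age in SJL leg, SJL EOM, Balb leg and Balb EOM. They were 296 and 478 for strain in leg at 10 and 12 months, 405 and 264 in EOM, and 15 and 8 for strain by age in leg and EOM. By camera 3 of the 35 list calls were lost and 20 further lists passed, none of the 20 with an estimated correlation, and 6 of the 10 calls made with an estimated correlation were lost. With quantile normalization as well, in the same order, they were 680, 738, 163, 2882, 2717, 3952, 2261, 3376, 1992, 359, 394, 544, 207, 14 and 8. With the 4 arrays as a factor they were, for all but strain by age in leg, 457, 314, 58, 2621, 2092, 3600, 2242, 3084, 1480, 205, 205, 165, 118 and 2.

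Leaving out each array in turn gave 86 to 138 for strain in leg, 47 to 101 in EOM and 1 to 14 for their difference, 679 to 1202 for EOM against leg in Balb and 483 to 1270 in SJL. For age it gave 1597 to 2186 in SJL leg, 406 to 1253 in SJL EOM, 1112 to 1600 in Balb leg and 74 to 556 in Balb EOM. For strain at 10 and 12 months it gave 20 to 55 and 32 to 41 in leg, 16 to 34 and 25 to 40 in EOM, and for strain by age 0 to 1 in EOM by limma. Where this left 1 array in a group, that array was assumed to vary like the other groups.

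The slow-fibre list in EOM against leg in Balb had a mean of 0.829 with probe sets above 20000 left out, which removed most of its genes. Values that did not pass turned as follows, with the range over single arrays left out. The dimmer Aldoa probe set was 0.152 and 0.011 in Balb and SJL leg at 12 months with quantile normalization and 0.123 in Balb with median centring, and ranged from -0.738 to 0.026 in Balb and from -1.174 to 0.031 in SJL. Myh4 in SJL leg was 0.42 with quantile normalization, 0.351 with median centring and 0.974 with a pseudocount of 1, and ranged from -4.256 to 2.069. Cd55 in EOM against leg in SJL was -0.111 with quantile normalization, -0.08 with median centring, -0.052 with the replicate block, -0.474 on 10-month arrays and -0.057 without the 4 arrays with quantile normalization, and ranged from -0.064 to 0.146.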

Other observations

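Lists that passed in none of the strain and muscle comparisons by camera on all 22 arrays had adjusted p-values of 0.0556 to 0.994 in Balb EOM against leg, where their medians are given. These were 0.01 for 18 ribosomal protein genes, 0.14 for 57 genes of oxidative phosphorylation with the TCA cycle, 0.07 for 26 of fatty acid oxidation, -0.11 for 29 of glycogen with glycolysis, 0.49 for 14 of fast fibres and 0.12 for 24 immediate early with heat shock genes. They were 0.37 for 20 cell cycle genes, 0.32 for 13 of lymphocytes with NK cells, 0.48 for 14 of complement with its regulators, 0.27 for 23 of dysferlin with sarcolemma proteins and 0.39 for 21 EOM-associated genes. They were 0.32 for 15 of retina with lens and cornea, 0.42 for 5 of melanocytes, 1.14 for 6 of blood and 0.14 for 3 sex-linked genes. The test pointed down, against the sign of the median, for immediate early with heat shock genes, ribosomal proteins and sex-linked genes, and the mean was -0.06 for sex-linked genes. The lysosome list (28 genes, 0.36) and the list for atrophy with stress and metallothioneins (13 genes, 0.18, with a test that pointed down) passed only in the difference of the strain effect between muscles, with an adjusted p = 0.246 and 0.584 with an estimated correlation. Without the 4 replicate 1 arrays at 10 months, a setting chosen after the data were seen, both also passed for strain in leg, as did complement, fatty acid oxidation and immediate early with heat shock genes. With an estimated correlation none of the 5 did, with an adjusted p = 0.11, 0.179, 0.11, 0.11 and 0.291 in the order named. Abca4, a gene of photoreceptors, was higher in EOM than in leg by 2.73 (SE 0.29) in Balb and 3.08 (SE 0.29) in SJL. Opn1mw, a cone opsin, was lower, with log2 differences of -1.72 (SE 0.24) and -1.66 (SE 0.24).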
